A study of Arabidopsis thaliana with 80 samples.

How the data were processed

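RNA from rosettes was sequenced in 80 libraries of Arabidopsis thaliana, each from a pool of 5 plants. The labels say that roots were discarded, and that flower stalks were discarded at the reproductive stage, but they do not pair the collections ex1 to ex4 with stages. Libraries were grouped by accession, collection and time of day as labelled, which gave 28 groups, 24 of 3 libraries and 4 of 2. The labels hold no Col-0 ex1 evening replicate 2, Moj ex1 evening replicate 3, Vel ex3 morning replicate 3 or Col-0 ex4 evening replicate 3.

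Deposited values are in log2 units, for 33602 genes in each library, made by the authors with FastQC, HISAT2 and StringTie on the TAIR10 genome, with versions not given in the sources used here. The log scale, the offset of 1 and a quantile normalization are not stated and were read from the values. Values ran from 0 to 13.3, 5 upper quantiles differed by 0.0 between libraries, and column totals lay between 65882 and 66017. Taken back from base 2 and weighted by gene length, the sum per library was near that of an FPKM table, and under a natural log it was far above it. The plan assumed values still to be put on a log2 scale with an offset of 1. They already were, so they were used as deposited. On this scale a fold change of a gene with low values is understated. No counts are given, so depth per library is unknown and no interval or lower limit that needs it is given.

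Quantile normalization gives each rank the same value in every library, so a change in the most abundant genes cannot be seen beyond their rank. RBCS1A held rank 1 or 2 in all 22 libraries of ex1, and LHCB1.1 held a rank from 3 to 6. All 279 organelle-encoded genes were listed at 0 in every library, as were 4784 genes in all, and none of these was tested. The library kit does not mark strand, so overlapping genes cannot be told apart, and reads of near-identical copies such as LHCB1.1 and LHCB1.3, LTP3 and LTP4, or the RBCS genes are uncertain. Of the gene identifiers, 32835 matched the reference annotation, a later release of the same assembly. It was used for names and gene types only, and no coordinates are given because the values do not depend on them.

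Genes with a value of at least 1 in at least 3 libraries, 20880 in all, were fitted with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with 1 mean per group and 52 residual degrees of freedom. Tests were two-sided and moderated with a trend, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Contrasts weighted groups equally. Evening was compared with morning over ex1 to ex3 and within each. Successive collections were compared, with ex4 against ex3 in Col-0 and Vel. Bon, Moj and Vel were each compared with Col-0 over ex1 to ex3, and 3 F tests asked whether these differences depend on one another. Shares of variance are sequential sums of squares over ex1 to ex3. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

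The following were set before the data were examined: the model, the contrasts, 19 gene lists and the rule for naming genes. The lists are morning clock genes, day and evening clock genes, floral promoters, floral repressors, vernalization factors, cold response, heat response, drought and abscisic acid response, nuclear photosynthesis genes, flavonoid and anthocyanin synthesis, ultraviolet and high-light response, salicylic acid defence, jasmonate and wound response, glucosinolate metabolism, senescence, starch degradation, growth and shade response, flower organ markers and root markers. A list of secondary wall and xylem genes was added after the data were seen and has no list test. The 20 lists hold 247 members matched by locus. Of these, 238 carry the same symbol in the reference, and 9 were kept by locus under another symbol or none (RVE6, HSP17.6C, UGT75C1, GS-OH, A9, HSP70-4, HSP22.0, HB7 and 5MAT).

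Lists were tested with limma's camera at a preset correlation of 0.01 in 7 comparisons, and p was adjusted over all 133 tests. Of the 42 calls, 1 held with an estimated correlation, that of the day and evening clock genes for time of day. The limma test fry, which asks whether a list's genes move one way on balance and compares no list with other genes, called 94.

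Named genes passed the threshold, had a back-transformed mean of at least 5 over the higher arm (the rule was read as the mean over all groups of that arm) and the same sign in every pair of group means. The 6 largest rises and 6 largest falls were taken for time of day and the 4 and 4 largest for each collection and accession comparison, without pseudogenes, transposable elements and organelle genes. For each F test the 4 smallest p-values were taken. Up to 3 passing members of each list of a comparison were added by smallest adjusted p. CCA1, LHY, TOC1 and GI for time of day, FLC, FT, SOC1 and VIN3 for collection and accession, and FRI, AOP2 and AOP3 for accession were named whatever their result. For named genes, 461 differences of a change between accessions or collections were tested. Their p was adjusted over those 461 alone, and most of the genes had been chosen on the same data.

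The model was tested on simulated data of 20880 genes with 50 changed genes at each size. For time of day it recovered 72% at a log2 change of 0.25 and 98% at 0.5, for ex2 against ex1 64% and 96%, and for Bon against Col-0 42% and 86%. False calls were 4.64%, 2.72% and 6.86% of all calls. The simulation drew independent normal noise around each gene's mean. It had no correlation between genes or libraries, no floor at 0 and no quantile normalization, so these rates hold for that setting only. Alternatives were other pseudocounts, filters, variance models, scaling, a replicate block, a 2-fold minimum, fewer samples in the fit, and each replicate number and each library left out.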

Results

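Messenger RNA was profiled by RNA sequencing in rosettes of Arabidopsis thaliana grown outdoors in a common garden. The plants were the accessions Bon, Moj and Vel, natural lines from southern Spain, and Col-0, the laboratory line behind the reference genome. Tissue was taken in a morning window from 10:00 to 10:30 and in an afternoon window from 15:30 to 16:00, which the labels call evening, at up to 4 successive collections named ex1 to ex4. The series asks how expression in wild accessions changes over the day and over the life cycle in a natural setting. Each replicate was a pool of 5 plants, so p-values measure the spread between pools from 1 garden. The 80 libraries formed 28 groups, 24 of them with 3 libraries and 4 with 2, and ex4 held Col-0 and Vel libraries only. Values are in log2 units of a length-normalized expression estimate for 33602 genes, of which 20880 were tested. The table holds no counts, so the sequencing depth behind a value is unknown, and between 20428 and 22858 genes per library had a value above 0. Collection numbers could coincide with the day of RNA extraction, so a collection and its extraction batch cannot be told apart.

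Collection was the largest source of difference between libraries. It took a median of 27.2% of a gene's variance, accession took 13.4%, and time of day took 4.6%, while 12.5% remained between replicates. Combinations of factors took further shares, with medians of 6.7% for accession with collection, 4.8% for collection with time and 1.7% for accession with time. The first component of the principal component analysis held 34.9% of the variance and set ex1 apart from the later collections. Of the 80 libraries, 79 were most similar to another library of their own group. The exception was the library labelled Moj ex3 morning replicate 1, whose closest library was Vel ex3 morning replicate 1 (Pearson correlation 0.984 across genes). On an axis running from Moj at 0 to Vel at 1, that library had a median position of 1, and the other 16 Moj libraries lay between -0.03 and 0.04. It is kept under its label here. Every Moj value below that includes ex3 morning includes it, and so does every average over Moj and other accessions there. It also enters the spread per gene that all comparisons share, so it touches comparisons without Moj too. Without it the count for Bon against Col-0 was 13890 genes, and with it 13727.

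**Figure D1:**
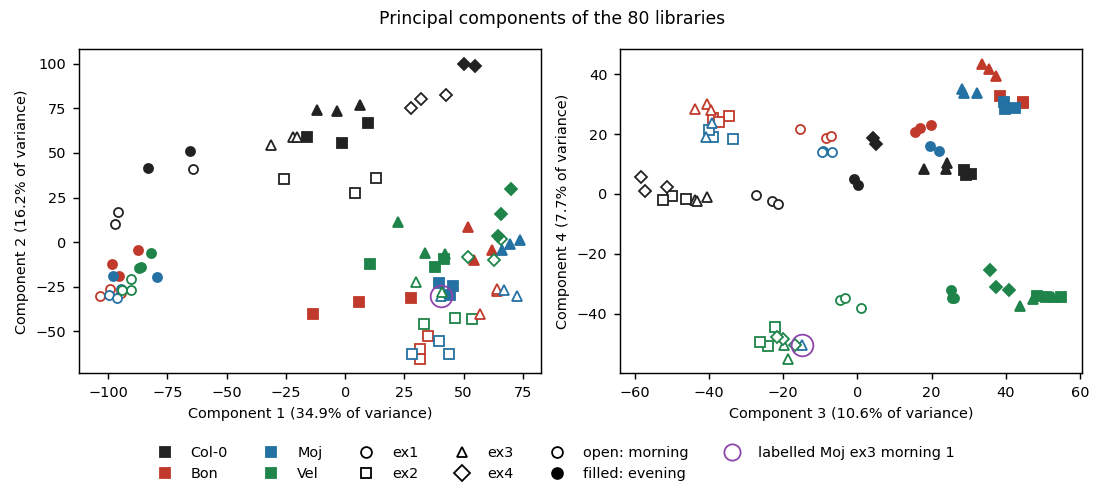
Scores of the 80 libraries on components 1 and 2 (left) and 3 and 4 (right), with the share of variance on each axis; colour gives the accession, shape the collection, and open or filled symbols the morning or evening. The ex1 libraries sit at the low end of component 1 (34.9% of variance), and the circled library, labelled Moj ex3 morning replicate 1, lies among the Vel libraries on component 4 (7.7% of variance).

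**Figure D2:**
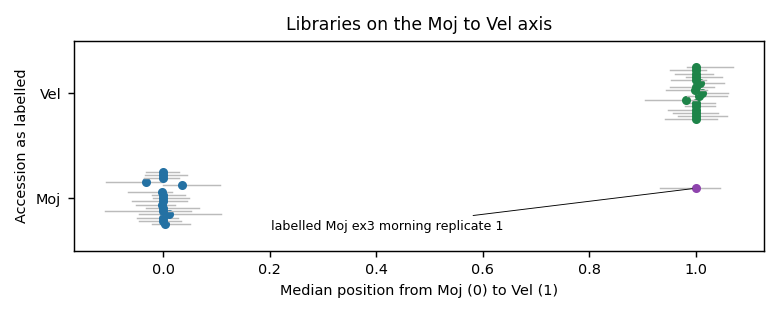
Position of each Moj and Vel library of ex1 to ex3 on an axis from Moj (0) to Vel (1), as the median over genes that separate the accessions, with grey lines for the quartiles. The library labelled Moj ex3 morning replicate 1 lies at 1, the other 16 Moj libraries between -0.03 and 0.04, and the 17 Vel libraries between 0.98 and 1.01.

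The comparison of evening with morning covered ex1 to ex3, with 34 evening and 35 morning libraries. Averaged over these collections, most genes of the dawn arm of the circadian clock fell towards the evening, and genes of its evening arm rose. LHY and CCA1, related MYB transcription factors at the core of the clock, fell by 4.67 (SE 0.048) and 4.44 (SE 0.055) log2 units, and RVE1, another member of that family, fell by 4.35. ELF4, a component of the evening complex, rose by 4.86 (SE 0.085), its partner LUX rose by 3.19, the blue light receptor FKF1 rose by 3.22, GI rose by 2.69 (SE 0.067), and TOC1, a repressor of the dawn genes, rose by 1.35 (SE 0.037). The largest fall was that of COL2, a CONSTANS-like gene, at -5.29 (SE 0.054). Other large falls were those of the adenosylmethionine decarboxylase gene AT5G15950 at -4.60, which overlaps an upstream reading frame annotated as a gene of its own, and of the hydrolase gene AT2G41250 at -4.35. Among the other large rises were AT1G07050, a CCT motif gene, at 4.85, AT2G23910 at 3.74 and the DnaJ-domain gene AT1G56300 at 3.42. All of these had a limma adjusted p of at most 2.9e-34 and the same direction in all 12 pairs of accession and collection.

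All 13 day and evening clock genes rose (median 1.35 log2 units, camera adjusted p = 1.1e-11, and 0.0031 with an estimated correlation). Of 11 morning clock genes, 9 fell and 2 rose (median -2.35, camera adjusted p = 1.7e-09, but adjusted p = 0.179 with an estimated correlation). Genes of starch breakdown rose in 11 of 12 cases (median 1.84, camera adjusted p = 6.5e-11; adjusted p = 0.179 with an estimated correlation), among them the phosphorylases PHS2 at 2.55 and PHS1 at 2.23 and the amylase AMY3 at 1.92. PHS1 was higher in the evening in 8 of 12 pairs only. Nuclear photosynthesis genes fell in 11 of 19 cases and rose in 2 (median -0.28, camera adjusted p = 0.0250; adjusted p = 0.786 with an estimated correlation), led by the light-harvesting genes LHCB2.1 at -1.92, LHCB1.1 at -1.75 and LHCB2.2 at -1.70. The evening differences of these genes changed from ex1 by -2.24, -1.60 and -2.20 in ex2 and by -3.54, -3.36 and -3.01 in ex3. Their averages therefore do not describe ex1. Reads of LHCB2.1 and LHCB2.2, and those of LHCB1.1 and its copy LHCB1.3, are hard to assign because the copies are near-identical. LHCB1.1 also sat among the 6 highest genes of all 22 ex1 libraries, where each rank has the same value in every library.

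The cold, growth and shade, heat, ultraviolet and jasmonate lists gave no camera call for time of day. Of 15 cold response genes, 11 rose and 4 fell (camera adjusted p = 0.0631). The transcription factor gene CBF2 fell by 2.79, COR27 rose by 3.05 and COR413-PM1, a membrane protein gene, rose by 1.19. In the growth and shade list 5 of 9 genes fell and 1 rose (camera adjusted p = 0.298), with PIF4 at 1.17, PIF5 at -1.01 and the auxin gene IAA19 at -0.62, the first 2 being related transcription factors of shade growth. The evening difference of PIF4 changed from ex1 by -2.73 in ex2 and -1.51 in ex3. Of 11 heat response genes, 2 rose and 3 fell (camera adjusted p = 0.634). The list's median was 0.03 and its mean -0.13, and HSFA7A changed by -1.15, HSP101 by -0.42 and HSFA2 by 0.35. Of 9 ultraviolet and high-light genes, 4 rose and 4 fell (camera adjusted p = 0.947), including the vitamin C gene VTC2 at -1.25, the ultraviolet receptor gene UVR8 at 0.67 and RUP1, a regulator of that receptor, at 0.60. RUP1 was higher in the evening in only 4 of 12 pairs, those of ex1, and changed by -0.58 (limma adjusted p = 6.8e-13) in ex2 and ex3 alone. Of 13 jasmonate genes, 3 rose and 3 fell (camera adjusted p = 0.994), with the biosynthesis gene OPR3 at 1.01, and the repressors JAZ1 at -0.90 and JAZ5 at -0.65. Counts adjusted over the list alone were 11 for the morning clock, 13 for the evening clock, 11 for starch, 13 for photosynthesis, 15 for cold, 6 for growth and shade, 5 for heat, 8 for ultraviolet and 6 for jasmonate.

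Across all genes, 7178 rose and 7349 fell towards the evening at a limma adjusted p under 0.05, and 828 of these 14527 changed at least 2-fold. The differences given are averages, and of 35 named genes 33 differed between ex1 and a later collection in their evening difference, 24 between an accession and Col-0, and 14 had pairs of both signs. Within single collections the count was 9661 in ex1, 13628 in ex2 and 12167 in ex3. LHY and CCA1 differed less in ex1 than in the later collections. LHY differed by -0.49 (SE 0.086) between evening and morning there, by -6.85 (SE 0.081) in ex2 and by -6.66 (SE 0.084) in ex3. CCA1 differed by -0.97, -6.21 and -6.14 in the same order. GI went the other way, with a rise of 5.10 in ex1, 1.55 in ex2 and 1.42 in ex3. PRR9, another dawn gene, rose by 1.48 in ex1 and fell by 3.21 in ex2.

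**Figure D3:**
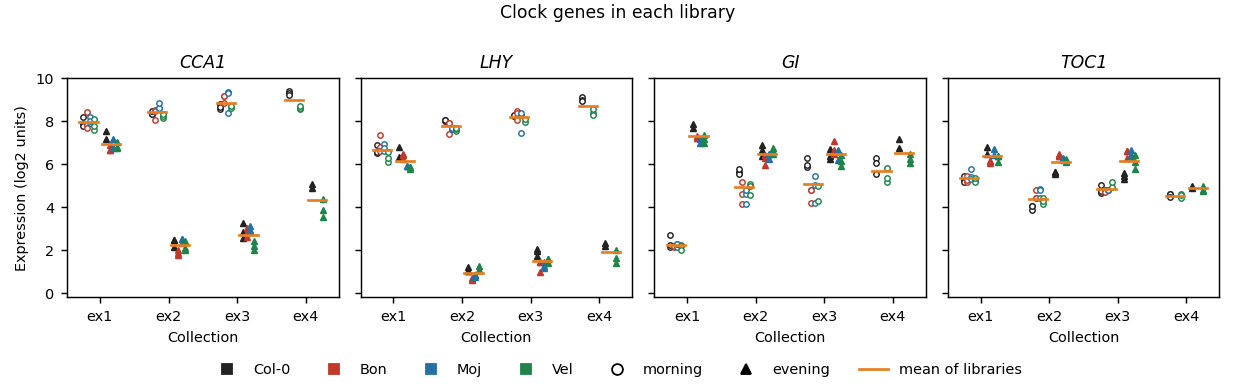
Expression in log2 units of CCA1, LHY, GI and TOC1 in each library, by collection and time of day; open circles are morning and filled triangles evening libraries, colour gives the accession, and orange bars are means over libraries. Evening values of LHY lie between 5.80 and 6.79 in ex1 and between 0.61 and 1.26 in ex2, while its morning values lie between 6.12 and 7.36 and between 7.42 and 8.08.

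From ex1 to ex2, defence genes rose and cold genes fell (24 against 22 libraries). PR1, a marker of the salicylic acid pathway, rose by 7.29 log2 units (SE 0.265), and LURP1, a pathogen response gene, by 5.55 (SE 0.188). SAG13, a gene of leaf senescence, rose by 5.94 (SE 0.157) and AT1G13470, of unknown function, by 5.89. The largest falls were in the methyltransferase gene AT5G44590 at -4.72 (SE 0.057), the LysM domain gene AT4G25433 at -4.35, LEA3, a late embryogenesis abundant gene, at -4.26 and the cysteine protease gene AT2G27420 at -4.21. All 8 had the same direction in all 8 pairs of accession and time, with a limma adjusted p of at most 1.9e-32. All 15 salicylic acid defence genes rose (median 2.79, camera adjusted p = 2.4e-09; adjusted p = 0.179 with an estimated correlation), among them the regulators WRKY70 at 3.25 and EDS1 at 1.97. All 10 senescence genes rose (median 1.89, camera adjusted p = 5.9e-05; adjusted p = 0.265 with an estimated correlation), including ORE1, a senescence transcription factor, at 2.43 and the chlorophyll breakdown gene NYC1 at 1.70. All 15 cold genes fell (median -2.44, camera adjusted p = 5.6e-06; adjusted p = 0.287 with an estimated correlation), including LTI30, a dehydrin, at -3.86, CBF2 at -3.50 and COR15B, a chloroplast protectant, at -2.44. COR15B stood among the 10 highest genes in 11 of 22 ex1 libraries and PR1 in 13 of 24 ex2 libraries, and the value at each of those ranks is the same in every library.

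The floral repressor FLC fell by 1.87 (SE 0.059) from ex1 to ex2, in 8 of 8 pairs. The floral promoter SOC1 rose by 0.55 (SE 0.080) on average, but in Col-0 its mean was 4.74 in ex1 and 4.47 in ex2. Its change was larger than in Col-0 by 1.17 in Bon, 1.31 in Moj and 1.12 in Vel (limma adjusted p of these differences 1.5e-05, 3.8e-06 and 3.1e-05). VIN3, which acts in the silencing of FLC after cold, rose by 0.70 (SE 0.082) on average and was higher in ex2 in 6 of 8 pairs, with evening means of 2.64 in ex1 and 2.502 in ex2 in Bon and of 4.27 and 4.096 in Col-0. FT, the mobile flowering signal, differed by 0.01 (SE 0.046, limma adjusted p = 0.856). Its values reached at most 0.235 in ex1 and 0.326 in ex2, so it was near 0 in both and a change could hardly be seen. Of 14 floral promoters, 11 rose and 1 fell (camera adjusted p = 0.0480; adjusted p = 0.517 with an estimated correlation), with SPL4 at 1.47, AGL24 at 0.99 and the photoperiod gene CO at -0.94. Of 13 repressors, 3 rose and 8 fell (camera adjusted p = 0.339), with SMZ at -1.62 and SNZ at -1.32. Of 4 vernalization genes, 2 rose and 1 fell (camera adjusted p = 0.634), the others named being VRN1 at 0.29 and VRN5 at -0.27. Photosynthesis genes fell in 17 of 19 cases (camera adjusted p = 0.0046; adjusted p = 0.757 with an estimated correlation), with LHCB1.1 at -1.54 and the Calvin cycle genes GAPB at -0.91 and PRK at -0.73. Drought and abscisic acid genes went both ways, 3 up and 7 down of 12 (camera adjusted p = 0.422), with DREB2A at -1.86, P5CS1 at -1.79 and NCED3 at -1.53. So did flavonoid genes, 8 up and 5 down of 15 (camera adjusted p = 0.979), with MYB12 at -1.65, FLS1 at -1.27 and CHI at -0.90. Of 11 heat genes, 4 rose and 1 fell (camera adjusted p = 0.443), including HSP90.1 at 1.38 and MBF1C at 1.37. As a check of the tissue, 4 of 6 flower organ markers rose (camera adjusted p = 0.447), SEP2 by 0.61, PI by 0.56 and A9, listed at 0 in every ex1 library, to a mean of 0.46. Of 8 root markers, PYK10 alone was high enough to test and fell by 1.24. In all, 8164 genes rose and 9025 fell, 3457 of them at least 2-fold. The changes given are averages over accessions, and in 32 of 41 named genes the change differed between at least 1 accession and Col-0 (limma adjusted p under 0.05). Counts adjusted over the list alone were 15 for salicylic acid, 10 for senescence, 15 for cold, 12 for promoters, 11 for repressors, 3 for vernalization, 18 for photosynthesis, 10 for drought, 13 for flavonoids and 4 for heat and for flower organs.

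From ex2 to ex3 the changes were smaller, with 281 genes at least 2-fold apart (23 against 24 libraries). LTP4 and LTP3, lipid transfer genes of near-identical sequence, rose by 4.64 (SE 0.233) and 3.92 (SE 0.234), the nudix hydrolase gene NUDT24 by 2.23 and CTL2, a chitinase-like gene of the secondary cell wall, by 2.18. The changes of LTP4 and LTP3 were larger than in Col-0 by 5.91 and 3.60 in Bon and by 6.32 and 3.79 in Moj (limma adjusted p of at most 4.8e-06). In Vel the mean of LTP4 went from 0.996 to 2.956, and in Col-0 from 1.809 to 3.24. The change of CTL2 was larger than in Col-0 by 3.01 in Bon and 2.94 in Moj (limma adjusted p 9.1e-08 and 1.6e-07), and in Vel it differed from Col-0 by -0.20 (limma adjusted p = 0.754). PR1 fell by 2.44 (SE 0.261), the lectin gene AT5G03350 by 2.67, the glycine-rich gene GRP9 by 2.33 and ARD3, of methionine salvage, by 2.19. All 8 genes named so far for this comparison had the same direction in all 8 pairs and a limma adjusted p of at most 1.3e-08. Salicylic acid genes fell in 14 of 15 cases (median -0.89, camera adjusted p = 1.5e-09; adjusted p = 0.179 with an estimated correlation), among them PR5 at -1.63, FMO1 at -1.52 and ICS1, the main salicylic acid synthesis gene, at -1.32. Cold genes rose in 12 of 15 cases and fell in 1 (camera adjusted p = 5.2e-06; adjusted p = 0.287 with an estimated correlation), with GOLS3 at 1.69, COR47 at 1.14 and CBF3 at 1.11. Flavonoid genes rose in 13 of 15 cases (camera adjusted p = 1.2e-04; adjusted p = 0.578 with an estimated correlation), with TT7 at 1.36 and CHS at 0.78. Floral promoters rose in 9 of 14 cases (camera adjusted p = 2.0e-04; adjusted p = 0.194 with an estimated correlation), with FUL at 1.12, SOC1 at 0.95 (SE 0.079) and FT at 0.43 (SE 0.045). FT had a mean of 0.11 in ex2 and 0.12 in ex3 in Col-0, and its change was larger than in Col-0 by 0.77 in Bon, 0.39 in Moj and 0.52 in Vel (limma adjusted p of these differences 6.4e-07, 0.0077 and 5.4e-04). FLC fell by a further 0.63 (SE 0.058) on average and VIN3 rose by 0.62 (SE 0.081). In Col-0 the mean of FLC was 0.16 in ex2 and 0.07 in ex3, so it had almost no room to fall there. The mean of FLC went from 3.56 to 2.81 in Bon, from 3.82 to 2.79 in Moj and from 2.83 to 2.13 in Vel. Of 12 drought genes, 6 rose and 1 fell (camera adjusted p = 0.0428; adjusted p = 0.757 with an estimated correlation), HB7 rising by 0.92 and RD20 by 0.88. Starch genes rose in 10 of 12 cases and fell in 1, morning clock genes rose in 7 of 11, and day and evening clock genes rose in 9 of 13 and fell in 2 (camera adjusted p = 8.8e-05, 4.8e-05 and 8.9e-04; adjusted p = 0.425, 0.287 and 0.239 with an estimated correlation). Of 19 photosynthesis genes, 5 rose and 9 fell (median 0.03, mean -0.18, camera adjusted p = 0.392), RCA by 0.69 and LHCB1.1 by -1.11. The flower organ genes SEP2 and PI, at 0.33 and 0.29, lost their calls under several settings, and accessions differed. Their morning means went from 0.15 to 1.65 and from 0.10 to 1.78 in Col-0, and from 2.01 to 1.40 and from 1.76 to 1.28 in Bon. Against Col-0 the change of SEP2 was lower by -1.79 in Bon and -1.35 in Moj, and that of PI by -1.75 and -1.67 (limma adjusted p of at most 0.0020 for each difference). In all, 5608 genes rose and 5465 fell. Of 41 named genes, 27 differed in their change between at least 1 accession and Col-0, and 20 had pairs of both signs. Counts adjusted over the list alone were 14 for salicylic acid, cold, flavonoids and photosynthesis, 9 for promoters, 7 for drought and for the morning clock, and 11 for starch and for the evening clock.

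From ex3 to ex4, compared in Col-0 and Vel with 11 libraries each, light-harvesting genes fell and the flowering signal rose. FT rose by 1.37 (SE 0.066), its paralog TSF by 1.73 (SE 0.245), SOC1 by 0.64 (SE 0.117) and FUL by 0.62, while FLC differed by -0.27 (SE 0.086) and VIN3 by -0.41 (SE 0.120). FLC went from a mean of 2.13 to 1.66 in Vel and from 0.07 to 0.02 in Col-0, and these changes differed by -0.46 (limma adjusted p = 0.0210). In Col-0 it was above 0 in 2 of 6 ex3 libraries and 1 of 5 ex4 libraries, so it had almost no room to fall. This difference therefore cannot show that the accessions regulate FLC differently. Photosynthesis genes fell in 18 of 19 cases (median -1.05, camera adjusted p = 2.0e-11; adjusted p = 0.194 with an estimated correlation), LHCB1.1 by 2.69, LHCB2.2 by 2.64 and LHCB6 by 2.61. These 3 fell less in Vel than in Col-0, with differences of 2.03, 2.605 and 1.88 between the changes (limma adjusted p 1.4e-06, 2.1e-10 and 5.2e-07). In the same comparison 11 of 13 secondary wall and xylem genes, a list chosen after the data were seen, rose and 1 fell (median 2.63). The largest single changes were rises of LTP4 at 6.04 (SE 0.344), the peroxidase gene PER64 at 4.72, the acyltransferase gene AT5G22490 at 4.24 and IQD10 at 4.05, and falls of the germin gene GER3 at -5.02 (SE 0.314), LHCB2.3 at -4.57, AT2G10940 at -3.90 and the defensin-like gene AT3G05730 at -3.63. These 8 had the same direction in all 4 pairs and a limma adjusted p of at most 4.5e-17. Senescence genes rose in 8 of 10 cases (camera adjusted p = 0.0184; adjusted p = 0.579 with an estimated correlation), with SAG12, a cysteine protease of ageing leaves, at 2.95. Cold genes fell in 11 of 15 cases (camera adjusted p = 0.0113; adjusted p = 0.708 with an estimated correlation), with COR15B at -1.36 and COR15A at -1.34. Flavonoid genes rose in 10 of 15 cases and fell in 2 (camera adjusted p = 0.0476; adjusted p = 0.808 with an estimated correlation), with the regulators PAP1 at 1.44 and TT8 at 1.39 and the enzyme FLS1 at -1.52. All 6 flower organ genes fell (camera adjusted p = 0.0454; adjusted p = 0.757 with an estimated correlation), AP3 by 0.89, PI by 0.86 and AG by 0.47, from low values. These 3 changes were smaller in Vel than in Col-0, with differences of 1.06, 1.21 and 0.71 between the changes (limma adjusted p 0.0225, 0.0047 and 0.0029). Floral promoters went both ways, 5 up and 7 down of 14 (median -0.25, mean 0.03, camera adjusted p = 0.819), and heat genes rose in 7 of 11 cases (camera adjusted p = 0.0726), HSP70-4 by 2.22. In all, 6071 genes rose and 5452 fell, and of the 1024 at least 2-fold apart 403 rose and 621 fell. Of 40 named genes, 18 differed in their change between Vel and Col-0. FLC, VIN3 and COR27 (-0.68) lost their calls without replicate 2. Counts adjusted over the list alone were 18 for photosynthesis, 8 for senescence, 11 for cold, 12 for flavonoids and promoters, 6 for flower organs and 10 for heat.

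**Figure D4:**
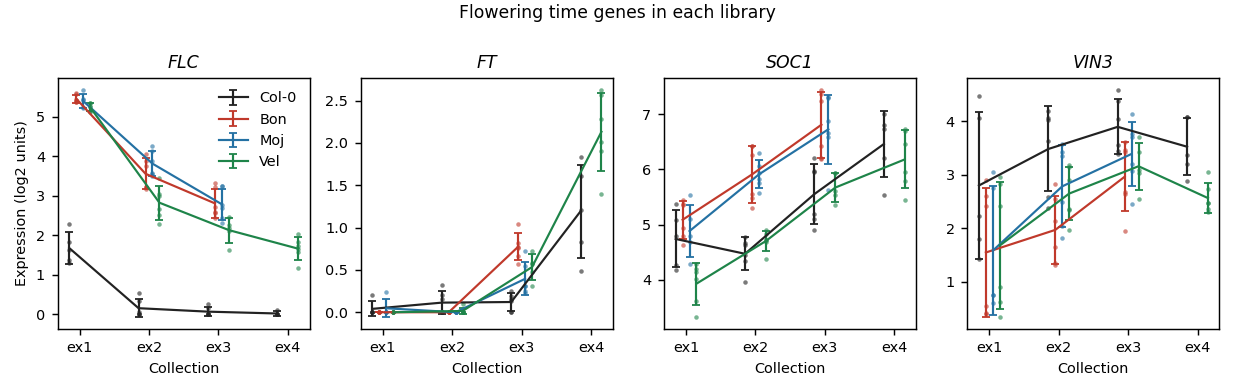
Expression in log2 units of FLC, FT, SOC1 and VIN3 by collection; points are libraries, lines join the means of each accession, and bars are 1 SD over its morning and evening libraries together. FLC fell from a mean of 5.46 to 2.81 between ex1 and ex3 in Bon and from 1.68 to 0.07 in Col-0, and FT reached 2.13 in ex4 in Vel.

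The accessions from southern Spain were set against Col-0 over ex1 to ex3 (18 Bon, 17 Moj, 17 Vel and 17 Col-0 libraries). FLC was higher in each, by 3.29 (SE 0.067) in Bon, 3.34 (SE 0.069) in Moj and 2.76 (SE 0.069) in Vel, in 6 of 6 pairs of collection and time. In Col-0 it was listed at 0 in 3 of 6 ex2 libraries and in 4 of 6 ex3 libraries. ESP, which turns glucosinolate breakdown towards nitriles, was higher by 6.54 (SE 0.113), 7.11 (SE 0.115) and 4.95 (SE 0.115) in the same order, and AOP2, a gene of glucosinolate side chains that the reference annotates as a transcribed pseudogene in Col-0, by 3.22, 3.26 and 2.70. AOP3 was listed at 0 in all but 5 of the 80 libraries and was not tested. PR1 was higher by 4.26 (SE 0.303), 4.47 (SE 0.309) and 4.89 (SE 0.309), in 6, 5 and 6 of 6 pairs. In ex1 mornings its mean was 1.85 in Moj and 2.46 in Col-0. Over both times of day its ex1 means were 3.81 in Bon, 2.13 in Moj, 4.91 in Vel and 1.75 in Col-0. In ex3 they were 9.10, 10.26, 9.88 and 2.57 in the same order, so the gap was wider in ex3 than in ex1. VIN3 was lower, at -1.31, -0.82 and -0.998, and SOC1 was higher in Bon (0.99) and Moj (0.92) but not in Vel (-0.17, limma adjusted p = 0.115). FT differed by 0.17 in Bon (limma adjusted p = 0.0039, in 2 of 6 pairs, and lost without replicate 2), by 0.06 in Moj and by 0.10 in Vel, the last 2 not past the threshold, though Vel passed with array weights (0.121, limma adjusted p = 0.0443) and with only the libraries compared (0.098, limma adjusted p = 0.0277). FRI, an activator of FLC, differed by 0.09 in Bon and -0.06 in Moj, neither past the threshold, and by -0.16 in Vel (limma adjusted p = 0.0105, lost without replicate 1).

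Among the largest differences, the non-coding RNA AT2G15555 was higher in all 3 accessions, at 6.11, 6.35 and 6.55. AT2G44240 was higher in Bon (6.68) and Moj (6.77), AT3G01345 in Bon (7.004), AT2G05914 in Moj (6.70), and AT2G15130 (6.78), AT5G41660 (5.69) and AT5G15360 (5.28) in Vel. AT1G24996 and AT1G25175 had mean values of 6.92 and 6.82 in Col-0 and of at most 0.22 in each accession. AT1G25098 differed by -6.17 in Vel. Bon was lower in AT1G76960 (-6.29) and ECS1 (-6.16), Moj in AT2G25510 (-7.95) and AT5G42530 (-7.42), and Vel in AT5G21020 (-6.61). Every one had a limma adjusted p of at most 4.9e-21 and the same direction in 6 of 6 pairs.

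Salicylic acid genes were higher in 15 of 15 cases in Bon and in Moj and in 14 of 15 in Vel (camera adjusted p = 1.6e-07, 5.9e-08 and 5.9e-08; adjusted p = 0.194 with an estimated correlation in each), among them EDS1 at 1.31, 1.42 and 1.36. These are averages over ex1 to ex3. The change of EDS1 from ex1 to ex2 was larger than in Col-0 by 1.46, 1.12 and 1.32 (limma adjusted p of at most 1.6e-05), so its gap depended on the collection. Flavonoid genes were lower in 14 of 15 cases in each accession (camera adjusted p = 8.8e-08, 7.5e-06 and 8.1e-09; adjusted p = 0.343, 0.493 and 0.287 with an estimated correlation), with PAP1, a MYB activator of anthocyanin genes, at -2.82, -2.85 and -3.43. The regulator TT8 was lower by -2.75 in Bon and -2.25 in Moj, and the enzyme genes DFR and LDOX by -3.36 and -3.16 in Vel. Cold genes were lower in 14 of 15 cases in Bon and Moj (camera adjusted p = 1.3e-05 and 8.0e-05; adjusted p = 0.309 and 0.412 with an estimated correlation) and in 7 of 15 in Vel (camera adjusted p = 0.237), with KIN1 at -2.57, -3.42 and -1.92. Of 20 glucosinolate genes tested, 12 were higher and 4 lower in Bon (camera adjusted p = 0.0243; adjusted p = 0.765 with an estimated correlation), 10 and 5 in Moj (camera adjusted p = 0.0934) and 4 and 12 in Vel (camera adjusted p = 0.399), where GS-OH was lower by -2.96. Floral repressors gave no camera call (adjusted p = 0.755, 0.286 and 0.422). In Bon the list's median was -0.28 and its mean 0.09, with MAF5 at 1.89. MAF3 was at -3.47 in Moj, and MAF2 and MAF4 were at -1.18 and -1.63 in Vel. Floral promoters gave none either (0.793, 0.544 and 0.432), with FD, a partner of FT, at -0.86, -0.89 and -1.01. Across all genes, Bon had 6790 higher and 6937 lower, Moj 6816 and 7311, and Vel 6617 and 6622, with 1839, 1825 and 1503 at least 2-fold apart. Counts adjusted over the list alone, for Bon, Moj and Vel, were 15, 15 and 15 for salicylic acid, 14, 14 and 14 for flavonoids, 15, 15 and 8 for cold, 17, 15 and 16 for glucosinolates, 10, 11 and 11 for repressors and 9, 10 and 5 for promoters. Reads of an accession were matched to the Col-0 genome, so genes that differ in sequence or are absent can read low, and the kit does not mark strand.

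**Figure D5:**
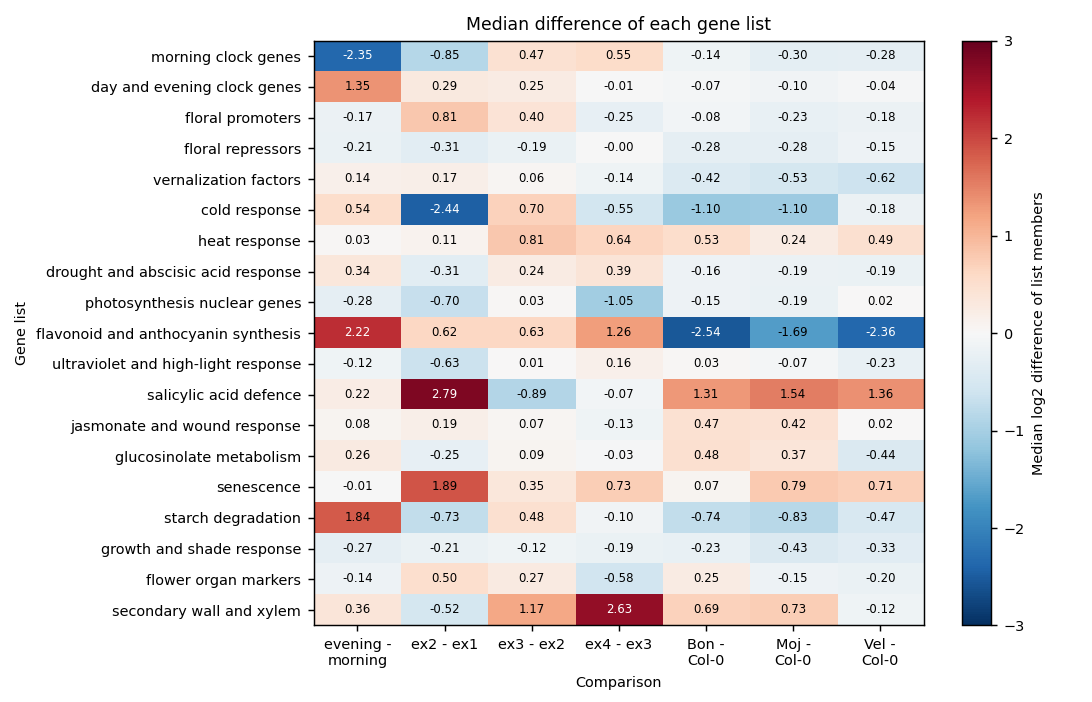
Median log2 difference of the tested members of 19 gene lists (vertical axis) in 7 comparisons (horizontal axis), with colour from -3 to 3 and the value in each cell. Flavonoid and anthocyanin genes have a median of 2.22 for evening against morning and of -2.54, -1.69 and -2.36 in Bon, Moj and Vel; the secondary wall list was chosen after the data were seen.

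The design also asks whether these differences depend on one another. The evening difference varied between collections in 14705 genes (limma F test, adjusted p under 0.05), and the smallest p-values belonged to LHY, CCA1, LZF1, a light-regulated zinc finger gene, and AT3G55580. LZF1 had a mean of 7.11 in the evening (SD 0.088, n = 3) against 1.11 in the morning (SD 0.022, n = 3) in Bon ex1, and of 5.84 against 4.80 in Bon ex2. The evening difference varied between accessions in 5270 genes. AT4G27360, a dynein light chain gene, had a morning mean of 4.94 (SD 0.137, n = 3) and an evening mean of 0.14 (SD 0.238, n = 3) in Col-0 ex3. In the other accessions its ex3 morning means were 0.28 in Bon, 0.42 in Moj and 0.84 in Vel, and its ex3 evening values were listed at 0 in Bon and Vel and had a mean of 0.01 in Moj. The annotated pseudogenes AT1G42690 and AT5G34838 were high in Bon, with ex1 morning means of 4.45 (SD 0.161, n = 3) and 4.78 (SD 0.153, n = 3) and evening means of 2.998 and 3.23, and listed at 0 in every ex1 library of Col-0. AT3G60930 had ex1 means of 3.20 in the morning and 1.62 in the evening in Col-0 and was listed at 0 in every ex1 library of Moj and Vel. Each gene named for this test was thus at or near 0 in some accession, with almost no room for an evening difference there. These values therefore cannot show that the accessions regulate such a gene differently over the day. The collection difference varied between accessions in 14577 genes. AT5G62240, a microtubule-associated gene, had ex1 morning means of 4.25 (SD 0.10, n = 3) in Vel and 4.18 (SD 0.284, n = 3) in Moj and was listed at 0 in all 3 Bon libraries of that group. Its ex2 morning values were listed at 0 in Vel and Bon and had a mean of 0.07 in Moj. At 0 in ex1 mornings, it had no room to fall in Bon, so the same limit holds. The pseudogene AT1G49090 had a morning mean in Bon of 1.67 in ex1 (SD 0.223, n = 3) and 5.04 in ex3 (SD 0.269, n = 3), against 0.12 and 0.09 in Col-0. The count for accession and time fell to 1467 genes without replicate 2 and was 10201 with array weights, and that for accession and collection was 9635 without replicate 2.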

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

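The tests of mixed or exchanged material, of an earlier clock phase, of the wrong label, the mixture and the swap, and of genes higher in an accession were chosen only after the result was seen; the splits of the samples, the test of single libraries for LHY and that of genes lower in an accession were planned before it.

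The evening difference differed between collections in 14705 genes and between accessions in 5270 genes, and the collection difference differed between accessions in 14577 genes. Among the named genes, those below differed between groups by more than 4-fold in limma's test against that size.

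Clock genes had another evening difference in ex1 than later, changing from ex1 by -6.36 in ex2 and -6.17 in ex3 for LHY, -5.25 and -5.17 for CCA1, and -3.55 and -3.67 for GI. In 7 of 24 clock genes (among them GI, LUX and PRR5) the difference was larger in ex1, which argues against mixed or exchanged morning and evening material. With any 1 library left out, the ex2 change of LHY stayed at 6.303 or more in size. This test decides nothing, since the change averages all accessions and 1 library could not move it far. The library values do answer it: LHY lay between 5.801 and 6.788 in all 10 ex1 evening libraries. In all 12 ex2 evening libraries it lay between 0.61 and 1.265, so no single library accounts for the change. An earlier clock phase in ex1 may contribute and stays open: day and evening genes were at a median of -0.235 in ex1 against ex2 mornings, with members from -2.70 to 0.97 and 9 of 13 lower, while in evenings all 11 morning genes were higher in ex1 (median 1.81). The season, the weather of each collection and the extraction batch were not tested and cannot be told apart here.

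Other genes whose evening difference changed from ex1 were the starch phosphorylases PHS1 (3.57 in ex2 and 3.49 in ex3) and PHS2 (3.09 and 2.72). The others were the adenosylmethionine decarboxylase gene AT5G15950 (-3.2 and -4.16), the ultraviolet response gene RUP1 (-3.56 and -3.52), AT2G23910 (3.13 in ex2) and PIF4 (-2.73 in ex2). The light-harvesting genes LHCB1.1 (-3.36), LHCB2.2 (-3.01) and LHCB2.1 (-3.54) changed by more than 4-fold in ex3. In ex2 they changed by -1.60, -2.20 and -2.24, without a call in the test against 4-fold. LHCB1.1 held a rank from 3 to 6 in all 22 ex1 libraries, where each rank has a fixed value, so its ex1 difference was held by its rank. LTP4 rose more from ex2 to ex3 in Bon (5.91) and Moj (6.32) than in Col-0. From ex1 to ex2, PR1 (4.46) and SAG13 (3.47) rose more in Moj than in Col-0.

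The library labelled Moj ex3 morning replicate 1 lay at a median position of 1 from Moj (0) to Vel (1) over 229 genes that separate the other libraries. That value argues against a mixture of both and is what a wrong accession label would give, so a wrong label is a candidate explanation. The lowest of the 17 Vel libraries of ex1 to ex3 lay at 0.982, so no partner for a swap is among those. The genes were chosen with these libraries included, which favours positions near their labels. The Vel libraries of ex4 were not placed on this axis. The library was kept under its label, and no biological explanation was tested.

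For genes at least 2-fold apart from Col-0, sequence divergence from the Col-0 reference or deletion may contribute and stays open, and differences between accessions in regulation were not tested. The share of these genes higher in the accession was at least 52.5%, which decides nothing, since the distribution of values shared by all libraries sets rises against falls. Genes at 1 or more in every Col-0 library and at 0 in every library of all 3 accessions numbered 0, and so did the reverse, so the ratio written for this test is void, and the rule for too few genes came after that result was seen. For single accessions the counts at 0 in the accession and at 0 in Col-0 were 4 and 14 for Bon, 9 and 2 for Moj, and 50 and 12 for Vel. Without the library labelled Moj ex3 morning replicate 1 they were 15 and 15 for Moj.

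In each of 13 comparisons 1 of 100 splits, the real one, gave as many genes, which is the lowest share 100 splits can give. Exchanged labels therefore rarely gave such counts, though for ex4 against ex3 another split came close. For the 3 F tests, exchanging the labels of time or collection also removed the average difference. Those splits therefore cannot tell a dependence between factors from that average difference. The real count and the highest of the other splits were 14527 and 3025 for time of day, 9661 and 3661 within ex1, 13628 and 6141 within ex2, and 12167 and 2122 within ex3. They were 17189 and 8889 for ex2 against ex1, 11073 and 2531 for ex3 against ex2, and 11523 and 10482 for ex4 against ex3. They were 13727 and 7055 for Bon, 14127 and 7985 for Moj, and 13239 and 2842 for Vel. For the 3 F tests they were 14705 and 6041, 5270 and 2118, and 14577 and 6385.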

How the results depend on the processing

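The fit of ex2 and ex3 alone, and that without the 3 libraries of largest residual spread, were chosen after seeing the data. Array weights raised the count for accession and time from 5270 to 10201 genes. With a 2-fold minimum the counts fell, by construction, to 828 for time of day, 1187, 1768 and 1286 within ex1, ex2 and ex3, 3457, 281 and 1024 for the collections, 1839, 1825 and 1503 for Bon, Moj and Vel, and 2933, 418 and 4953 for the F tests. Leaving out replicate 2 moved 2 counts by over 1.5 times from their value with all libraries: that for accession and time, whose range was 1467 to 6273 (without Col-0 ex1 morning replicate 3), and that for accession and collection, whose range was 9635 to 15214 (without Moj ex3 morning replicate 1). That for ex4 against ex3 went from 11523 to 7689 without replicate 2. Fewer samples were in these fits, and the 2 ranges cover only fits with libraries left out. With array weights the count for accession and collection was 17681. No single library moved a count by 1.5 times. Where a group of 2 was left with 1 library, that lone library is assumed to vary like the other groups. List calls numbered 42, 1 with an estimated correlation and 94 with fry. RUP1 reversed to -0.581 in ex2 and ex3 alone, since its rise was in ex1. Of 255 named gene results, 11 changed their side of the threshold or direction in 1 or more of 15 settings, the 2-fold minimum left out. These made 20 changes over results and settings, mostly of SEP2 and PI (ex3 against ex2) and without replicate 2, and the cause was not tested. The filter at 5 covered 235 of these results and ex2 and ex3 alone 35. Median-ratio scaling used factors from 0.958 to 1.054. The replicate block gave 14312 genes for time of day, 9064 within ex1 (9661 without it) and 4683 for accession and time. The labels do not say what a shared replicate number means. Residuals of 38 morning and evening pairs with the same number had a median correlation of 0.052, and 12 were over 0.1. For 76 pairs with different numbers the median was -0.001, and 19 were over 0.1. In ex1 all 10 pairs with the same number were above 0, from 0.002 to 0.383, and not every library there correlated best with its own number. Such pairs were above 0 in 6 of 12 cases in ex2, 3 of 11 in ex3 and 4 of 5 in ex4. Quantile normalization moved nothing, since the values already are so normalized, and the count alternative was not run, since the table holds no counts. Depth is unknown, so its limit could not be given.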

Other observations

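The list of secondary wall and xylem genes was chosen only after the result was seen; the flavonoid list was planned.

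All 15 flavonoid and anthocyanin genes rose towards the evening over ex1 to ex3 (median 2.22, camera adjusted p = 1.1e-11; adjusted p = 0.194 with an estimated correlation), and 15 did so adjusted over the list alone. Within ex1 10 of them rose (median 0.69), within ex2 15 (median 3.08) and within ex3 15 (median 2.69). CHS, the entry enzyme of the pathway, was higher in the evening in each accession, by 0.27 to 0.83 in ex1 and by 2.51 to 3.98 in ex2. DFR, an enzyme of the anthocyanin branch, was higher in the evening in ex2 by 2.12 in Col-0, 3.73 in Bon, 4.47 in Moj and 5.01 in Vel, and differed by -0.16 in Moj in ex1. CHS and DFR within single accessions were not tested.

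Secondary wall and xylem genes, which build the thickened walls of water-conducting cells, fell in 9 of 13 cases from ex1 to ex2 (median -0.52). All 13 rose from ex2 to ex3 (median 1.17), and 11 rose and 1 fell from ex3 to ex4 (median 2.63). CESA7, a cellulose synthase gene of these walls, went from a mean of 1.15 in ex2 to 4.44 in ex3 in Bon, from 1.43 to 4.25 in Moj, from 0.83 to 1.44 in Col-0 and from 0.93 to 1.102 in Vel. Its ex4 means were 5.31 in Col-0 and 4.46 in Vel. LTP4 went from 0.03 in ex2 to 7.36 in ex3 in Bon and from 1.81 to 3.24 in Col-0. In the library labelled Moj ex3 morning replicate 1, CESA7 was at 1.42 and LTP4 at 3.70, below the other 5 Moj ex3 libraries.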
